A study of Mus musculus with 18 samples.

How the data were processed

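CUT&Tag libraries for NFIA and NFIB were made from mouse granule neuron progenitors at postnatal day 7, hyperplasia at postnatal day 28 and medulloblastomas of adult mice, isolated on a Percoll gradient, with 100000 cells per library, per the labels' protocols. There were 18 libraries, from 3 stages, 2 targets and 3 preparations each. Reads were aligned with Bowtie2 to mm10 and peaks called with MACS2, per the submitters' processing notes, which give no versions; whether a control library was used is not given in the sources used here. The deposited lists hold the summits of each library called separately, each 1 base wide, with the −log10 p-value that the authors' peak caller gave as its score. The lowest score in any list was 2.00, so that sites below it are missing from the lists, and a gene or region with no summit is one with none listed. Neither reads nor coverage were used, so depth is unknown, and no interval or floor from counting error was computed.

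Stage and target were taken from the sample titles. In 6 of the 18 libraries the name of the deposited data carries the other target, and in 12 another replicate number. Preparations of GNP and hyperplasia share 2 title dates (numbers 1 and 2 the first, number 3 the second), and the 3 tumor preparations have 3 other dates. Summits on the 19 autosomes were ranked by score, and the 30000 highest of each library were kept, since list lengths differ between libraries and do not measure binding. Ties in score were broken at random with a fixed seed (1; the alternative used 2). Ties mattered most in the second NFIA library of hyperplasia, where 20.4% of the top summits had the score of the last summit kept.

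Each top summit was given to the nearest of 20665 protein-coding gene spans of the RefSeq table of assembly GRCm38.p6 within 100 kb, and the 2 libraries of a preparation were summed. The table gives gene spans without strand, exons or sequence, so nearest gene spans took the place of the planned nearest start sites. Location classes were within 1 kb of either gene end, further inside a gene or between genes. The planned motif search was not run. All 195 distinct list genes matched the table by symbol. Coordinates are mm10, 1-based.

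Genes with a mean of at least 2 summits over the 9 preparations were tested with limma 3.58.1 in R 4.3.3 (trend and empirical Bayes) on log2(summits + 0.5), in 1 fit over all preparations with stage as the only term and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of genes with few summits. Summit numbers per gene are small whole values. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 13 lists and 3 contrasts, with an estimated correlation as an alternative, with which the neural stem and progenitor calls did not hold. Also run was fry, which asks whether the genes of a list move on balance and does not compare them with other genes, and gave this list an adjusted p of 0.0265 in both contrasts with tumors. NFIA and NFIB were compared per library with stage as a term, in genes with a mean of at least 1 summit per library, and the interaction of stage and target in the same way with 6 groups. The lists were SHH pathway, granule progenitor identity, granule neuron differentiation, NFI family, cell cycle, neural stem and progenitor, medulloblastoma genes, astrocyte and Bergmann glia, oligodendrocyte lineage, microglia and macrophage, vascular and meningeal, Purkinje cell and interneuron, and non-neural tissues.

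Regions were made by widening the top summits of all libraries by 100 bp on each side, merging them and keeping those hit by at least 3 libraries. Their counts were set beside those of all 10 splits of the 6 preparations of a pair of stages. Location shares and list lengths were compared with exact permutation tests over preparations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

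The gene test was tested on simulated data for each contrast, with 100 of 8546 genes changed 2-fold and 100 changed 4-fold. Counts were Poisson draws around the mean of each gene, whose spread was not matched to the real preparations. The shares recovered hold for that setting only. For hyperplasia against GNP, tumor against GNP and tumor against hyperplasia, the test recovered 6%, 10% and 5% of the 2-fold changes. It recovered 38%, 41% and 44% of the 4-fold changes, with 0 false calls. Of the 4-fold changes in genes with a mean of at least 8 summits, 83.3%, 86.4% and 94.7% were recovered. The region count recovered 198, 192 and 196 of 200 planted regions among 40000. This recovery depends on how strongly the planted regions were made to differ between stages, which is not given here. The recovery therefore does not measure how sensitive the count is in the real libraries. The number of unplanted regions that met the criterion is not given either, so false calls among regions cannot be judged.

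The genes named were fixed by rule before the data were examined, as were the groups, the tests, the gene lists and 60 alternatives. For each stage contrast they were, of the genes past the threshold whose preparations did not overlap, up to 10 with the largest fold in each direction; from each list the members with the smallest p, up to 4 that passed or else 2; and 19 fixed genes, of which 1 is not reported here. For regions they were the 3 with the best worst rank among those in all 6 libraries of a stage and none of the other. The text gives the examples among these that describe each group.

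The alternatives fixed beforehand were the 15000 highest summits, all summits scaled to equal totals, scores of at least 5, NFIA or NFIB libraries alone, the 12 libraries with matching labels, the replicate number as a block, a pseudocount of 2, no filter, other assignments of summits to genes, chromosome X added, list length as a covariate, 18 libraries with an estimated correlation, other overlaps and criteria for regions, each stage alone, 2.5 kb around gene ends, and leaving out each preparation. Added after the data were seen were leaving out the second NFIA library of hyperplasia, the 3 libraries least similar to the rest, or chromosome 6, single title dates, date as a term, the 6 preparations of a contrast alone, another seed for ties, preparations or targets taken from the data names, and leaving out each preparation in the interaction.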

Results

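Genome-wide positions of the nuclear factor I proteins NFIA and NFIB were compared across the formation of mouse medulloblastoma, a tumor of the cerebellum. The assay was CUT&Tag, in which an antibody directs a transposase to cut the chromatin around a bound protein. The 18 libraries covered 3 stages: granule neuron progenitors (GNPs, the cells that give rise to cerebellar granule neurons) at postnatal day 7, hyperplasia at postnatal day 28, and tumors of adult mice. Stage and age thus changed together, and no difference between stages below can be told apart from one of age. Each stage had 3 preparations, and each preparation gave 1 library for NFIA and 1 for NFIB from 100000 cells. The preparations are labelled as separate samples, but nothing says that they came from separate animals, so that p-values measure the spread between preparations, which may be technical. The design text also names a cell line, which was not analysed here.

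The deposited values were lists of peak summits, each with the −log10 p-value of the authors' peak caller as its score. A library held between 49948 and 385466 summits. The number with a score of at least 10 ran from 3059 to 29949. The read depth behind the lists is unknown, so the 30000 highest-scoring autosomal summits of each library were compared. The mean log2 length of the lists differed by 0.43 for hyperplasia against GNP, 0.86 for tumor against GNP and 0.43 for tumor against hyperplasia. The exact permutation p-values were 0.7, 0.1 and 0.6, two-sided, where 0.1 is the smallest possible with 3 preparations against 3, so that the tests could not show a difference. No pair of libraries looked like the same library deposited again, since at most 0.537% of the top summit positions were identical between any pair.

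Libraries of the same stage shared more regions of NFIA and NFIB summits with each other than with libraries of other stages. Whether NFI proteins bind these regions was not tested, since no motif search was run and no control library is known. Merging the top summits gave 42017 regions hit by at least 3 libraries, of which 6112 (14.5%) held a summit in all 18. Of these common regions, 34.0% lay within 1 kb of a gene end, 36.5% further inside a gene and 29.5% between genes. Those with the best worst rank included regions next to Ubxn6 (chr17, 56079207 to 56079524, 32 bp from the gene), Rab40c (chr17, 25919899 to 25920208, 339 bp) and Zbtb20 (chr16, 42875283 to 42875750, 173 bp), a zinc-finger repressor of the developing brain, and a region 55575 bp from the growth factor gene Pdgfa (chr5, 138920145 to 138920733). These 4 were picked from the highest-ranked regions after their values were seen.

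The Jaccard index, the share of regions held in common by a pair of libraries, averaged 0.589 within a stage and 0.535 between stages (exact permutation of the stages over the 9 preparations, two-sided p = 0.00357). Each pair of stages alone gave the smallest p that 3 preparations against 3 allow, 0.1 by exact permutation. The mean was 0.626 within GNPs, 0.571 within tumors and 0.568 within hyperplasia (12 pairs each), and whether these differ was not tested. The hyperplasia mean includes the second NFIA library of that stage, which stood apart, with a mean index of 0.470 to the other libraries of its stage, and 58.1% of its top summits lay in the regions.

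**Figure D1:**
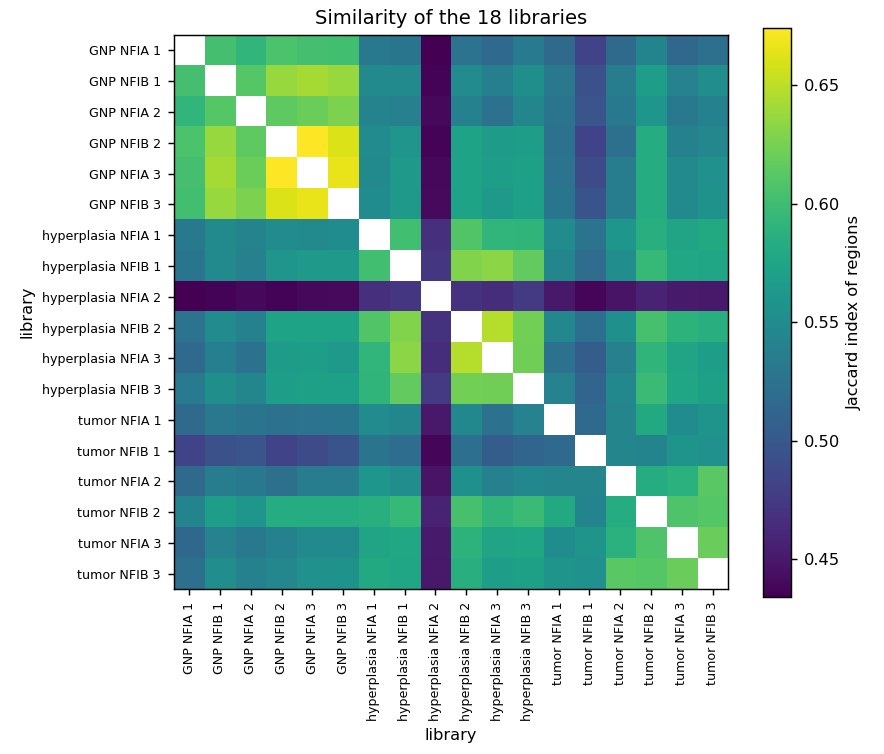
Jaccard index of the merged regions for every pair of the 18 libraries, named by stage, target and replicate on both axes; colour gives the index and the diagonal is left blank. The mean within GNPs is 0.626, and the second NFIA library of hyperplasia is the darkest row and column (mean 0.470 within its stage).

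The comparison of hyperplasia with GNPs asked which sites of NFIA and NFIB summits differ between these stages. Hyperplasia gained 904 regions and lost 1167, out of 42017, relative to GNPs. A region counted as gained with a summit in at least 5 of the 6 hyperplasia libraries and at most 1 of the 6 GNP libraries, and as lost in the opposite case. Gained regions lay inside genes in 46.2% and between genes in 47.3% of cases, and lost regions in 48.3% and 44.5%. Near a gene end lay 6.42% of gained and 7.20% of lost regions. Few genes were called as changed in their number of assigned summits: 6 rose and 3 fell among 8546 tested. The test recovered only 6% of simulated 2-fold changes for this contrast, so a low count does not show that few genes changed.

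Slc7a5, which encodes a transporter of large neutral amino acids (chr8, 121881146 to 121907686), fell from 14.3 ± 0.577 summits in GNPs to 5.33 ± 1.15 in hyperplasia (SD, n = 3 preparations, log2 fold change −1.37, SE 0.15, limma adjusted p = 0.0491). The adhesion receptor gene Adgrd1 (chr5, 129096750 to 129204599) fell from 19.7 ± 1.53 to 10.3 ± 0.577, and Nr1h4, the bile acid receptor, from 5 in every preparation to 2. Slc38a11 and Dnah3, which encodes a heavy chain of axonemal dynein, had no summit listed among the top summits of any GNP library, and had means of 3.67 ± 1.15 and 4.33 ± 0.577 summits in hyperplasia (limma adjusted p = 0.00507 and 0.0188). Nod2, a sensor of bacterial cell wall fragments (chr8, 88647315 to 88688474), rose from 2 to 5 summits, and the chromatin remodeller gene Ep400 from 2 to 4. Foxn4, a forkhead factor of retinal and spinal progenitors, and Manea each rose from 2 to 4.33 ± 0.577.

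Regions present in all 6 libraries of hyperplasia and in none of GNPs numbered 158, and 192 showed the opposite. The 3 best-ranked gained regions lay inside Dicer1, the microRNA-processing nuclease (chr12, 104719005 to 104719414), 51951 bp from Cdca2 (chr14, 67620989 to 67621470) and 38065 bp from Bcar3 (chr3, 122381456 to 122381928). The Dicer1 region held no top summit in the tumor libraries either. The Cdca2 and Bcar3 regions were hit in 6 and 5 of the 6 tumor libraries. The 3 best-ranked lost regions lay 22164 bp from Pgm1 (chr4, 100009305 to 100009612), inside Zfp423, a zinc-finger gene of cerebellar development (chr8, 87836978 to 87837265), and inside Vps13d (chr4, 144936571 to 144937040).

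No member of a fixed gene list passed the threshold over all genes in this comparison. Of 17 measured genes of granule progenitor identity, 13 had a lower and 3 a higher fitted value in hyperplasia (camera adjusted p = 0.117 over 39 tests), and 2 passed when adjusted over the list alone. They held the transcription factor genes Pax6 (16.3 ± 1.53 summits in GNPs, 8 ± 2 in hyperplasia, limma adjusted p = 0.101) and Meis1 (13.3 ± 3.21 and 6.33 ± 1.53, 0.121). Of 18 genes of granule neuron differentiation, 11 were lower and 7 higher (0.591), with 1 past the threshold adjusted over the list alone; the neurogenic factor gene Neurod2 had 7.33 ± 0.577 and 3.67 ± 0.577 summits (limma adjusted p = 0.0951). Lost regions made up 10 of the 167 regions nearest to genes of granule neuron differentiation (5.99%, against 2.62% of all regions assigned to a gene, Fisher's exact p = 0.0129, adjusted 0.475), among them 2 each at Rbfox3, Grm4, Snap25 and Nfasc.

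Among the 14 measured members of the SHH pathway, which drives GNP proliferation, 9 were lower and 5 higher (camera adjusted p = 0.861); Gli2 had 46.7 ± 4.16 summits in GNPs and 37 ± 4.36 in hyperplasia, Ptch1 9.33 ± 1.15 and 8 ± 1.73. The 4 NFI genes themselves had 2 higher and 2 lower values (0.861), with 48 ± 3.61 and 53.7 ± 3.51 summits at Nfia and 26.7 ± 4.04 and 26 ± 1.73 at Nfib. Gli1 and Gabra6 had too few summits to be tested. The lists of cell cycle (18 measured, adjusted p = 0.964), neural stem and progenitor (11, 0.861) and medulloblastoma genes (15, 0.367) did not differ from the other genes by more than the test could show. Of the markers of other cells, those of vessels and meninges were all lower (5 of 5 measured, camera adjusted p = 0.104), with 7.33 ± 1.53 summits in GNPs and 5 in every hyperplasia preparation at Pecam1. Astrocyte and Bergmann glia (8, 0.964), oligodendrocyte (8, 0.993), microglia (2, 0.993), Purkinje cell and interneuron (10, 0.591) and non-neural lists (2, 0.629) held no gene past the threshold over all genes. For the astrocyte list the test and the mean (0.12) were above 0 and the median (−0.00) was not, and for the oligodendrocyte list the test and the median (−0.06) were below 0 and the mean (0.01) was not. The Purkinje cell and non-neural lists each had 1 member past the threshold adjusted over the list alone, and the remaining 9 lists had 0.

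The gene counts came from limma's test on log2(summits + 0.5) across 9 preparations with Benjamini-Hochberg adjustment, which placed 1136 genes at an unadjusted p under 0.05. The count of 9 genes became 12 when ties in score were broken differently, 0 with all summits scaled to equal totals, 41 with the 15000 highest-scoring summits (none of the 9 genes among them). It was 44 and 50 with NFIA or NFIB libraries alone, 4 without the second GNP preparation, 1 without the second hyperplasia preparation, 1 with list length as a covariate, 0 with scores of at least 5 and 3 with a pseudocount of 2. Of the 9 genes, 7 had identical counts in all preparations of some stage, against 25.8% of all tested genes. With all summits scaled, the log2 fold changes of Nod2, Manea, Nr1h4 and Ep400 were −0.17, −0.01, −0.05 and 0.08. GNP and hyperplasia preparations shared title dates. Preparations of the first date alone gave 229 genes and 319 gained and 506 lost regions (4 of 4 libraries against none). Those of the second date alone gave 2367 and 2222 regions (2 of 2 against none). Date as a term gave 3 genes, with Dnah3 the only one of the 9 among them (Slc38a11 was below the filter there). Gained regions outnumbered lost ones with all summits (2052 and 1428) and without the second NFIA library of hyperplasia (1522 and 1313), the reverse of the counts above. Without that library the criterion asked for fewer hyperplasia libraries. Fisher's exact test per region called 0 regions, with 1445 at an unadjusted p under 0.05. It could hardly have called any, since its smallest possible p with 6 libraries against 6 is 0.00216, and it counts both libraries of a preparation as separate.

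**Figure D2:**
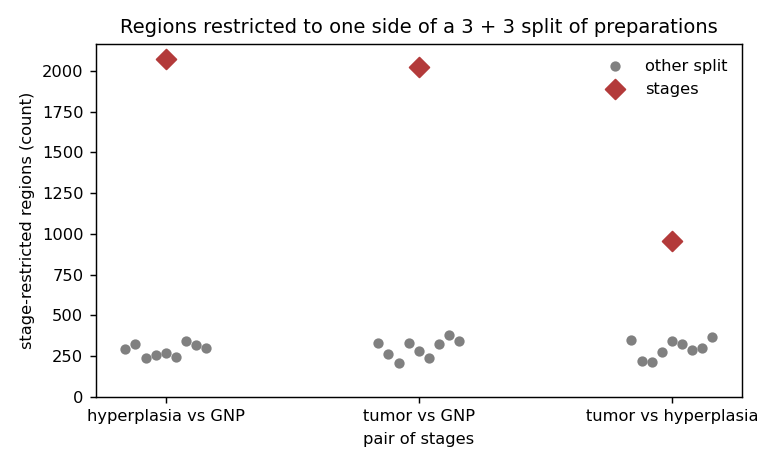
Number of regions restricted to either side when the 6 preparations of a pair of stages are split 3 against 3, for the 3 pairs of stages on the horizontal axis; diamonds show the split by stage and grey points the other splits. The stage splits give 2071, 2023 and 956 regions, and the highest of the other splits give 341, 380 and 366.

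The comparison of tumors with GNPs asked which sites differ between the malignant cells and normal progenitors. Tumors gained 967 regions and lost 1056 relative to GNPs. Among 8546 genes, 8 rose and 5 fell. The largest fall was at Agbl4, which encodes a carboxypeptidase that trims glutamates from tubulin (chr4, 110397649 to 111664324): it went from 15 ± 2 summits in GNPs and 12 ± 1.73 in hyperplasia to 1.67 ± 0.577 in tumors (SD, n = 3 preparations, log2 fold change −2.87, SE 0.23, limma adjusted p = 0.0113). Ptprn2, a phosphatase-like receptor of secretory granules (chr12, 116485695 to 117278167), rose from 20.7 ± 0.577 to 38.3 ± 2.52 summits (0.87, SE 0.09, limma adjusted p = 0.0192).

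The other genes that fell were Sugct, a mitochondrial CoA-transferase (chr13, 16857472 to 17694795, from 7.67 ± 1.53 to 2 summits, log2 fold change −1.69), Map3k13 (11.3 ± 1.53 to 4.67 ± 0.577), the salt-inducible kinase gene Sik1 (12 in every GNP preparation, 7 in every tumor) and Grhpr, a glyoxylate reductase (5 ± 1.73 to 1). Add2, which encodes a protein of the membrane skeleton (chr6, 86028681 to 86124409), rose from 3.67 ± 0.577 to 14.3 ± 2.08 summits (1.83, SE 0.23, limma adjusted p = 0.0399). The centromere protein gene Cenpu rose from 2 to 5.33 ± 0.577, Nod2 from 2 to 6 ± 1, Ep400 from 2 to 4 and the chondroitin sulfotransferase gene Chst13 from 2 to 4. Slc38a11 and Dnah3, with no top summit listed in GNPs, had 3.33 ± 0.577 and 2 ± 1 in tumors.

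**Figure D3:**
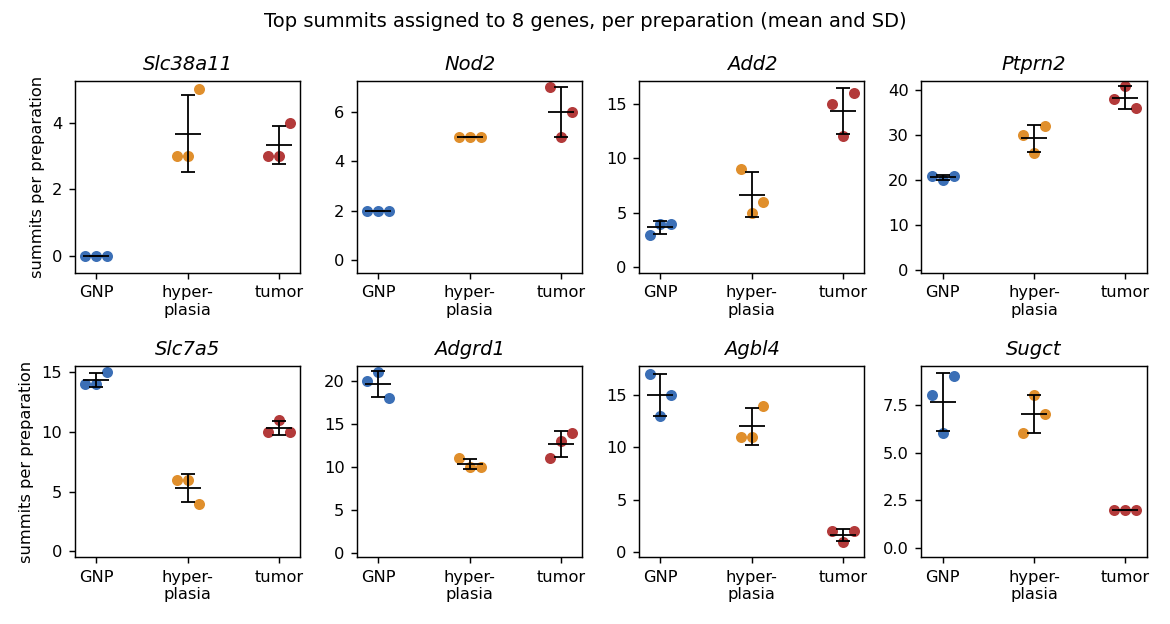
Top summits assigned to 8 of the called genes in each preparation, the sum of its NFIA and NFIB library, by stage; points are preparations and bars the mean and SD (n = 3). Agbl4 goes from a mean of 15 in GNPs to 1.67 in tumors, and Ptprn2 from 20.7 to 38.3.

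Chromosome 6 held a larger share of the tumor summits. On average 7.06% of the top summits of tumor libraries lay there, against 5.24% in GNPs and 5.37% in hyperplasia, a ratio of tumors to GNPs of 1.35 ± 0.03 (SD, n = 3 preparations); among tumor preparations the lowest and highest ratios were 1.31 and 1.37. The exact permutation p against the other 6 preparations was 0.0238, the smallest that 3 against 6 allow (0.113 adjusted over 19 autosomes). Chromosomes 5, 7 and 19 reached the same p with ratios of 0.956, 0.953 and 0.915, and the ratio of chromosome 6 was the farthest from 1 of the 19. Gained regions made up 5.74% of the regions of chromosome 6 and 2.09% of the others. Of the genes named for this comparison, Add2, Chst13, Smo, Foxp2, Atoh1 and Ccnd2 lie on chromosome 6, and the median log2 fold change of its 488 tested genes was 0.31, against −0.02 for the other genes. Without chromosome 6 there were 11 genes and 825 gained and 1030 lost regions.

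**Figure D4:**
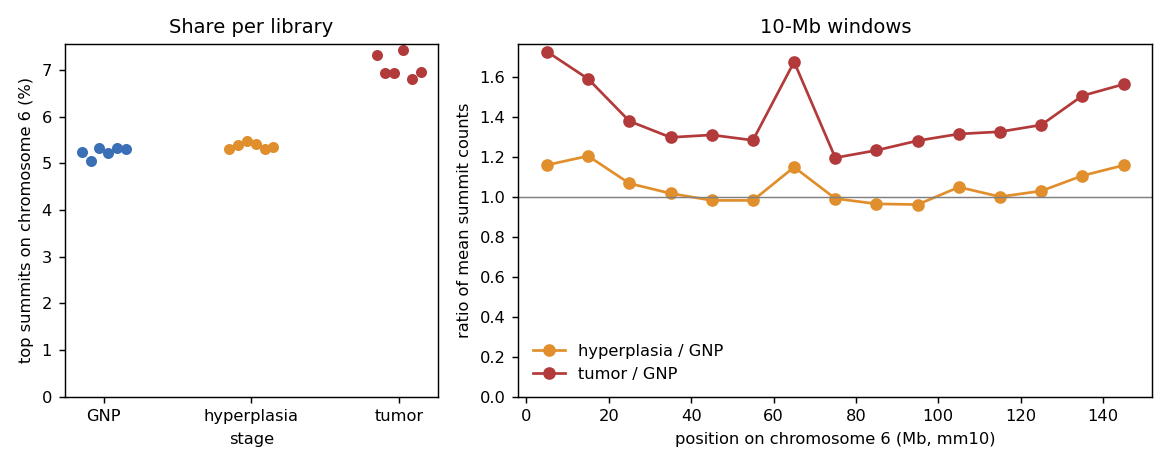
Left, percent of the 30000 top summits on chromosome 6 in each library by stage; right, ratio of mean summit counts to GNPs in 10-Mb windows along chromosome 6 (mm10) for hyperplasia and tumor. All 15 tumor windows lie above 1, between 1.20 and 1.73.

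Regions in all 6 tumor libraries and in no GNP library numbered 170, with 155 in the opposite direction. The 3 best-ranked gained regions were all on chromosome 6: one with no gene within 100 kb (43859332 to 43859872), one 14922 bp from Tspan11 (127872261 to 127872914) and one 19007 bp from Tril (53839656 to 53840009), each also hit in all 6 hyperplasia libraries. The 3 best-ranked lost regions lay inside Nckap5 (chr1, 126484645 to 126485071), and on chr7 (51307811 to 51308072) and chr13 (15078650 to 15079528) with no gene within 100 kb. Near gene ends lay 6.51% of gained and 14.8% of lost regions.

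Of the fixed lists, the neural stem and progenitor genes had more summits in tumors than in GNPs (median log2 fold change 0.34, 10 of 11 measured genes higher, camera adjusted p = 0.0292). The call was lost with an estimated correlation (camera adjusted p = 0.308), although the correlation estimated for the list, −0.041, lay below the preset 0.01. None of its members passed over all genes and 2 passed adjusted over the list alone. The list held Sox1, a marker of neural progenitors (3.33 ± 0.577 summits in GNPs, 8 ± 1.73 in tumors, limma adjusted p = 0.0696), and Id1, an inhibitor of differentiation (1.33 ± 0.577 and 3.33 ± 0.577, 0.11), while Sox2 had 5.67 ± 1.15 and 3.67 ± 0.577. The call was also lost with the 15000 highest-scoring summits, with NFIA or NFIB libraries alone, and without the first GNP, the third hyperplasia or the second tumor preparation, and with all summits scaled to equal totals the median was −0.25; over all alternatives tried for this list the adjusted p ran from 0.00694 to 0.784.

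The NFI genes had 3 of 4 higher values in tumors (camera adjusted p = 0.195), with 34 ± 2.65 summits at Nfib against 26.7 ± 4.04 in GNPs, 18.7 ± 4.73 at Nfic against 13 ± 1.73, and 56 ± 7.21 at Nfia against 48 ± 3.61. In the SHH list (14 measured, 7 higher and 7 lower, 0.861), 1 gene passed adjusted over the list alone. Smo, the signal transducer of the pathway, had 3.33 ± 0.577 summits in GNPs and 6.33 ± 0.577 in tumors (limma adjusted p = 0.107), Gli3 7.67 ± 3.21 and 3.67 ± 0.577, and Ccnd1 5 ± 1 and 8 ± 1.73. Granule progenitor identity (17 measured, 0.993) had 3 members past the threshold adjusted over the list alone and no common direction, since its median was 0.06 and its mean −0.13. Atoh1, the master regulator of granule progenitors, had 5.33 ± 0.577 and 8.33 ± 1.53 summits, whereas Pax6 had 16.3 ± 1.53 and 9.67 ± 1.15 and Meis2 6.33 ± 2.08 and 0.667 ± 0.577 (limma adjusted p = 0.0924). Granule neuron differentiation (18 measured, 11 lower, 0.442) had 1 such member, with 7.33 ± 0.577 and 3.33 ± 0.577 summits at Neurod2 (limma adjusted p = 0.0678) and 13 ± 4.58 and 7.67 ± 0.577 at Snap25. Lost regions made up 9 of its 167 regions (5.39% against 2.34% of all, Fisher's exact p = 0.0173, adjusted 0.475) and 6 of the 89 regions of granule progenitor identity (6.74%, Fisher's exact p = 0.0183, adjusted 0.475).

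The lists of cell cycle (18 measured, camera adjusted p = 0.993), medulloblastoma genes (15, 0.861), astrocyte and Bergmann glia (8, 0.993), oligodendrocyte lineage (8, 0.993), microglia (2, 0.861), vessels and meninges (5, 0.993), Purkinje cells and interneurons (10, 0.993) and non-neural tissues (2, 0.629) were not called. The medulloblastoma, Purkinje cell and non-neural lists each had 1 member past the threshold adjusted over the list alone. Foxp2, a factor of Purkinje cells, had 6 ± 2 and 13.3 ± 1.53 summits (limma adjusted p = 0.0922); for its list the median (0.03) was above 0 and the mean (−0.19) was not.

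The 13 genes came from the same limma fit (1250 genes at an unadjusted p under 0.05), and became 29 when ties in score were broken differently, 41 with the 15000 highest-scoring summits (none of the 13 among them), 312 with all summits scaled (3 of the 13 among them). It was 32 and 62 with NFIA or NFIB libraries alone, 25, 4 and 8 without GNP preparation 1, 2 or 3, 4 and 6 without tumor preparation 1 or 2, 1 with list length as a covariate and 4 with scores of at least 5. Of the 13 genes, 9 had identical counts in all preparations of some stage. With all summits scaled, the log2 fold changes of Nod2, Sugct, Ep400 and Add2 were −0.42, 0.04, 0.11 and 0.24, that of Agbl4 was −0.70 (limma adjusted p = 0.192) and that of Ptprn2 0.04 (0.870). The call of Ptprn2 was kept in 11 of 25 alternatives. The 3 tumor preparations carry 3 title dates of their own, so that stage and date cannot be told apart, and Fisher's exact test per region, with the same lowest possible p, called 0 regions (1357 at an unadjusted p under 0.05). With all summits 1627 regions were gained and 1639 lost. Without tumor preparation 1, where the criterion asked for fewer tumor libraries, gains outnumbered losses (2239 and 1696).

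Regions that hyperplasia and tumors both gained against GNPs numbered 323, and regions both lost numbered 530. Since both comparisons use the same GNP libraries, unchanged groups were simulated against them, which gave a mean of 25.3 shared gains (highest 42 of 100 simulations) and 15.1 shared losses (highest 27). Independent lists of these sizes would share 20.8 and 29.3 regions. In the region simulations every library had the same chance of a summit in a given region, whereas the real libraries were unequal. The share of top summits inside the regions was 58.1% in the second NFIA library of hyperplasia and 71.8% in the first NFIB library of tumors. The region simulations therefore set no firm baseline. Of the called genes, Slc38a11, Ep400, Dnah3 and Nod2 were higher in both comparisons (0.00562 for independent lists, a mean of 0.01 in the simulations). None was lower in both (0.00176 for independent lists, where 3 and 5 genes were lower by limma). Each of the shared genes had identical counts in all GNP preparations, which both comparisons use. With all summits scaled, the log2 fold changes of Ep400 and Nod2 were 0.08 and −0.17 for hyperplasia and 0.11 and −0.42 for tumors. The simulated gene counts were Poisson draws, whose spread was not matched to the preparations, so the gene simulations set no firm baseline. Across all tested genes, which are not independent replicates, the fold changes correlated at 0.621 (0.439 simulated), with a covariance of 0.151 against a simulated 0.147.

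The comparison of tumors with hyperplasia asked which sites differ between the abnormal stages. Tumors gained 508 regions and lost 448 relative to hyperplasia. Whether the pairs of stages differ in these numbers was not tested. Without the 3 least similar libraries there were 1730 and 1578 here, against 1522 gained and 1313 lost for hyperplasia against GNP. With libraries left out the criterion asks for fewer of them, and more were left out here, so these counts cannot be ranked. Of 8546 genes, 2 rose and 3 fell. Agbl4 fell from 12 ± 1.73 to 1.67 ± 0.577 summits (SD, n = 3 preparations, log2 fold change −2.56, SE 0.23, limma adjusted p = 0.0389), Sugct from 7 ± 1 to 2 (−1.58, SE 0.17), and Sik1 from 11.7 ± 0.577 to 7 (−0.70, SE 0.07). Both genes that rose lie on chromosome 6: Ccser1 (61179960 to 62382863) went from 7 in every hyperplasia preparation to 14 ± 1 summits, and Tmem178b (39871230 to 40255150) from 19.3 ± 1.15 to 32.3 ± 2.52.

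The 3 best-ranked regions found in all 6 tumor libraries and in no hyperplasia library lay inside Pip4k2b (chr11, 97723499 to 97723882), Ddx31 (chr2, 28882918 to 28883275) and the netrin gene Ntn3 (chr17, 24208701 to 24209429). The Pip4k2b region was also present in all 6 GNP libraries. The lost regions with the best ranks were the Dicer1 region named above, a region inside Ppara, the fatty acid sensor (chr15, 85762950 to 85763261), and a region on chr9 (82609989 to 82610323) with no gene within 100 kb. Chromosome 6 carried 80 of the 508 gained regions (3.23% of its regions, against 1.08% of the others).

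The neural stem and progenitor genes had more summits in tumors than in hyperplasia as well (11 of 11 measured higher, median log2 fold change 0.28, camera adjusted p = 0.0292). This call too was lost with an estimated correlation (camera adjusted p = 0.308), although the correlation estimated for the list, −0.041, lay below the preset 0.01. None of its genes passed over all genes and 1 passed adjusted over the list alone; Sox1 had 4.33 ± 0.577 summits in hyperplasia and 8 ± 1.73 in tumors (limma adjusted p = 0.214) and Notch1 10.3 ± 1.53 and 12.3 ± 1.53. The median became −0.10 with all summits scaled, and the call was lost with the 15000 highest-scoring summits, NFIA or NFIB libraries alone, without the second NFIA library of hyperplasia, and without GNP preparation 1 or 2, hyperplasia preparation 3 or tumor preparation 2, with adjusted p from 0.0139 to 0.859 over all alternatives tried for this list.

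Granule progenitor genes had 13 of 17 higher values in tumors than in hyperplasia (camera adjusted p = 0.117), with 6.33 ± 1.53 and 12.3 ± 1.53 summits at Meis1 (limma adjusted p = 0.214). SHH pathway genes had 11 of 14 higher values (0.298), NFI genes 4 of 4 (0.367), among them Nfib with 26 ± 1.73 and 34 ± 2.65 summits, and vascular and meningeal genes 4 of 5 (0.104), among them Pecam1 with 5 and 7.67 ± 0.577. The NFI, vascular and astrocyte lists each had 1 member past the threshold adjusted over the list alone; Slc1a3, the glial glutamate transporter, had 15 ± 1.73 and 8.67 ± 2.89 summits (limma adjusted p = 0.248). The other lists were granule neuron differentiation (18 measured, camera adjusted p = 0.901), cell cycle (18, 0.861), medulloblastoma genes (15, 0.659), astrocyte and Bergmann glia (8, 0.993, with a median of 0.06 and a mean of −0.08), oligodendrocyte lineage (8, 0.993), microglia (2, 0.861), Purkinje cells and interneurons (10, 0.467) and non-neural tissues (2, 0.993).

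The 5 genes (937 at an unadjusted p under 0.05 in limma) became 10 when ties were broken differently, 8 with the 15000 highest-scoring summits, 11 and 22 with NFIA or NFIB libraries alone, 1 without chromosome 6, 0 without hyperplasia preparation 2 or 3, 3 without hyperplasia preparation 1, 2 and 1 without tumor preparation 1 or 3, 0 with list length as a covariate and 2 with scores of at least 5. With all summits scaled, the log2 fold changes of Sugct, Agbl4 and Tmem178b were −0.15, −0.42 and 0.14. Of the 5 genes, 3 had identical counts in all preparations of some stage. Tumor dates were again not shared with hyperplasia, and Fisher's exact test per region, with the same lowest possible p, called 0 regions (465 at an unadjusted p under 0.05). Lost regions outnumbered gained ones with all summits (990 and 638) and without the second NFIA library of hyperplasia (928 and 598), the reverse of the counts above. Without that library the criterion asked for fewer hyperplasia libraries.

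NFIA and NFIB libraries were compared to learn whether the related proteins differ in their sites. With targets taken from the sample titles, no gene differed between the 9 NFIA and the 9 NFIB libraries by limma with stage as a term (0 of 8546 genes, 482 at an unadjusted p under 0.05, lowest adjusted p 0.718). The genes closest to a difference were Slc45a4, with 2.67 ± 0.866 summits per NFIA and 4.33 ± 0.866 per NFIB library (SD, n = 9), and the GABA transporter gene Slc32a1, with 2.22 ± 0.972 and 1.11 ± 0.333; both were picked after their values were seen. In 6 of the 18 libraries the deposited name of the data carries the other target, so the comparison rests on labels in conflict. The 12 libraries with matching labels gave 4 genes, targets taken from those names 4, and GNPs, hyperplasia and tumors alone 63, 38 and 31.

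Whether a stage difference depended on the target was tested as an interaction in limma. It called 0 genes for hyperplasia against GNP (349 at an unadjusted p under 0.05), 0 for tumor against GNP (322) and 1 for tumor against hyperplasia (412). That gene was Tnfaip8l3. Its NFIA libraries held 1.33 ± 0.577 top summits in hyperplasia and none in tumors (SD, n = 3). Its NFIB libraries held none in hyperplasia and 1.67 ± 0.577 in tumors (difference of log2 fold changes −3.91, limma adjusted p = 0.0238). The counts were 5, 4 and 2 with the 15000 highest-scoring summits, and the last was 0 without the first hyperplasia preparation or without any of the tumor preparations, and 2 without the second hyperplasia preparation.

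The location of summits relative to genes was compared between the 3 stages. Of the top summits, 26.2% ± 1.39 in GNPs, 25.1% ± 2.01 in hyperplasia and 23.0% ± 2.09 in tumors lay within 1 kb of a gene end (SD, n = 3 preparations), against 3.06% of 100000 random autosomal positions. Summits further inside genes made up 40.3% ± 0.845, 40.4% ± 1.00 and 42.2% ± 0.733, and those between genes 33.5% ± 0.573, 34.6% ± 1.54 and 34.8% ± 1.36. The lowest tumor preparation inside genes (41.7%) lay above the highest of GNPs (41.3%) and of hyperplasia (41.2%), which gave an exact permutation p of 0.1 in both contrasts (two-sided, the smallest possible). With 3 preparations against 3 none of the 9 tests could pass the threshold (lowest adjusted p 0.45). With all summits the difference inside genes was −0.998 percentage points for tumor against GNP and −0.726 for tumor against hyperplasia, against 1.89 and 1.88 with the top summits.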

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

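The tests of exchanged targets, the title date, extra copies of chromosome 6, the number of high-scoring summits by target and gene loss were chosen only after the results were seen.

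In Tnfaip8l3 the tumor to hyperplasia difference in the NFIA libraries minus that in the NFIB libraries was −3.91 on the log2 scale, by an interaction test. The counts behind it were at most 2 summits per library. Among 32 ways of exchanging NFIA and NFIB within the 6 preparations, 10 called at least 1 gene, and the highest of the others called 10, so chance cannot be excluded. No biological explanation was tested for it.

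The second NFIA library of hyperplasia lay far from the other libraries of its stage in 3 measures. It held 362180 summits, against 64209 to 170971 in the others. Its mean Jaccard index was 0.470, against 0.572 to 0.596. Of its top summits, 39.2% lay between genes, against 32.9% to 34.6%. Across 8 measures, 24 groups of 6 libraries were tested and 3 were marked, all from this library, where chance marks about 1 in 20 (1.2 of the 24).

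Tumor libraries held a larger share of summits on chromosome 6, by a factor of 1.35 against GNPs. Low-scoring summits as the whole source are argued against by the ratio of 1.43 among the 15000 highest-scoring summits, and a few loci by a ratio above 1 in 100% of the 10-Mb windows (15 of 15; at most 61.5% on another chromosome). Among summits outside the 30000 highest-scoring, which hold more of the background, the ratio was 1.36, so that extra copies of chromosome 6 in the tumors may be the source. The other autosomes ran there from 0.832 (chromosome 11) to 1.19 (chromosome 3), a wider spread than among the top summits (0.915 to 1.02). The title date cannot be told apart from the stage, since all tumors have dates of their own, and the highest ratio of any GNP or hyperplasia library was 1.04. More NFI binding along the whole chromosome also stays open and was not tested.

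The target of 6 libraries is given differently by the title and by the name of the deposited data. In the first date, NFIA libraries by title held 5026 to 6449 summits with a score of at least 10. NFIB libraries held 21648 to 29949 (exact permutation p = 0.0286). By data name the groups of 6 and 2 gave an exact permutation p of 0.0714. Each p is the smallest that groups of its sizes allow, and neither test kept the libraries of a preparation paired, so this could not decide. Over all 18 libraries the permutation p was 0.0123 by data name and 0.0297 by title. Those permutations crossed preparations, stages and dates, so the sizes of the p-values do not show which labels separate the counts better. Same-target libraries of a stage were less alike than different-target libraries under both groupings, by −0.00634 by title (62 of 64 exchanges as large) and −0.0008875 by data name; the rule set beforehand, that the higher value marks the right labels, favoured the data names, but with both values below 0 there is no target signal to read, and a value above 0 was required only after this was seen. Which labels are right cannot be told apart here.

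Agbl4 and Sugct had fewer top summits in tumors, but not all windows that overlap them had fewer. Between 111500001 and 112000000 on chromosome 4 each GNP library held 4 to 7 top summits, each hyperplasia library 2 to 4 and each tumor library 0. On chromosome 13 the numbers were 1 to 2, 0 to 2 and 0 between 17000001 and 17500000. They were 2 to 4, 2 to 5 and 3 to 5 between 17500001 and 18000000. In every window of chromosome 13 from 15000001 to 17000000 the tumor mean lay below the GNP mean. Tumors had 0.167 against 4.5 between 15000001 and 15500000, and 0.667 against 2.67 between 16500001 and 17000000. Gli3 (15463723 to 15730026), which had fewer summits in tumors above without a call, lies in this stretch. Outside the 30000 highest-scoring, the 6 tumor libraries held 295 summits inside Agbl4 and 149 inside Sugct, but 276 and 138 of these came from the long, low-scoring lists of the NFIA libraries of the first and second tumor preparations (median scores 2.03 and 2.21). In the other 4 tumor libraries, Agbl4 held 0.00277% to 0.0104% of such summits, below every GNP library (0.0197% to 0.0299%). Sugct held 0.00139% to 0.00522% there, below the median of the GNP libraries (0.00704%) but within their range (0% to 0.0111%). The 0% came from the first NFIA library of GNPs alone. Loss of both copies can therefore neither be excluded nor told apart from lower NFI binding, since the libraries point in different directions and summits from non-tumor cells cannot be told from others. Loss of 1 copy was not tested.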

How the results depend on the processing

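The alternatives chosen only after the data were seen were leaving out the second NFIA library of hyperplasia, the 3 least similar libraries or chromosome 6, single title dates or date as a term, the 6 preparations of a contrast, other ties, groups or targets by data name, and leaving out preparations in the interaction. Values are given in the order hyperplasia against GNP, tumor against GNP and tumor against hyperplasia, and the cause of a change was not tested unless stated.

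The similarity of libraries within a stage kept its direction under every alternative tried, with differences from 0.0243 to 0.0622. The region counts stayed within 1.5 times under 250 bp on each side, fixed 1-kb windows, NFIB libraries only, other ties and without chromosome 6. A change within 1.5 times can still turn round which of gains and losses is larger. The gene counts (9, 13 and 5) moved under most alternatives, and the list counts (0, 1 and 1) under fewer.

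With the 15000 highest-scoring summits the genes numbered 41, 41 and 8 and the lists called for tumor against GNP and tumor against hyperplasia 0 and 0. With all summits scaled, 0 and 312 genes were called in the contrasts with GNP, and 0 and 0 lists in those with tumor. The log2 fold change was −0.17 for Nod2 and −0.011 for Manea in hyperplasia against GNP, −0.42 for Nod2 and 0.043 for Sugct in tumor against GNP, and the median of the neural stem and progenitor list −0.25 and −0.10 in the contrasts with tumor. NFIA libraries only gave 44, 32 and 11 genes and NFIB libraries only 50, 62 and 22, with 0 lists in the contrasts with tumor each time, as did an estimated correlation. The 12 libraries whose labels match gave 16 genes for hyperplasia against GNP and 8 for tumor against hyperplasia. A pseudocount of 2 gave 3 genes for hyperplasia against GNP. No filter gave 86, 108 and 36. Gene bodies plus 5 kb gave 6 for tumor against GNP. Chromosome X added gave 14, 33 and 8. List length as a covariate gave 1, 1 and 0, a score of at least 5 gave 0, 4 and 2; and 18 libraries with an estimated correlation gave 122, 165 and 13.

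Replicate number as a block gave 1, 2 and 0 genes and 0 genes for the interaction of tumor against hyperplasia. Deviations of preparations with the same number correlated across genes, which are not independent replicates, at no more than 0.0839, and numbers 1 and 2 share a date, so the numbers were not taken as pairs.

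Leaving out the second NFIA library of hyperplasia gave 3 genes for tumor against hyperplasia and 1 list for hyperplasia against GNP. Leaving out the 3 least similar libraries gave 17, 42 and 3 genes, and 1 list for hyperplasia against GNP and 2 for tumor against hyperplasia. Without chromosome 6 there was 1 gene for tumor against hyperplasia, where fewer genes were tested. For hyperplasia against GNP the first date gave 229 genes and date as a term 3. Preparations put together by data name gave 4 genes for hyperplasia against GNP and 3 for tumor against hyperplasia, and other ties 29 for tumor against GNP and 10 for tumor against hyperplasia. Leaving out each preparation gave 1 to 11, 4 to 25 and 0 to 4 genes, 0 to 1, 0 to 1 and 0 to 2 lists, and 0 to 1, 0 to 2 and 0 to 2 genes for the interaction, which with the 15000 highest-scoring summits were 5, 4 and 2. For NFIA against NFIB (0 genes) the 15000 highest-scoring summits gave 1, no filter 1, the 12 libraries whose labels match 4, targets by data name 4, and GNP, hyperplasia and tumor alone 63, 38 and 31.

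Gained and lost regions with the 15000 highest-scoring summits were 526 and 732 for hyperplasia against GNP and 590 and 628 for tumor against GNP, and 349 and 297 for tumor against hyperplasia. With all summits they were 2052 and 1428, 1627 and 1639, and 638 and 990, so that the balance of gains and losses turned round in the contrasts with hyperplasia. All 6 against none gave 158 and 192, 170 and 155, and 43 and 27, as a stricter criterion must give fewer. Fisher's exact test called 0 gained and 0 lost in each contrast (1445, 1357 and 465 regions at an unadjusted p under 0.05), which its smallest possible p of 0.00216 made almost certain. NFIA libraries only gave 552 and 1044 for hyperplasia against GNP and 501 and 296 for tumor against hyperplasia; the 12 libraries whose labels match gave 330 and 449, 463 and 376, and 194 and 103. Without the second NFIA library of hyperplasia they were 1522 and 1313 for hyperplasia against GNP and 598 and 928 for tumor against hyperplasia. Without the 3 least similar libraries they were 1522 and 1313, 2239 and 1696, and 1730 and 1578. Both settings ask for fewer libraries, and not equally in the contrasts. The first date gave 319 and 506, and the second date, with fewer libraries to meet, 2367 and 2222. Leaving out each preparation, which asks for fewer libraries, gave 1329 to 2216 gained and 1644 to 2206 lost, 1425 to 2239 and 1696 to 2143, and 879 to 1516 and 821 to 1530.

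The difference in summits near gene ends for hyperplasia against GNP was 0.446 percentage points with the 15000 highest-scoring summits and 0.503 without the 3 least similar libraries, against −1.09. That inside genes was −0.786 and −0.614 under the same alternatives and −0.272 with all summits, against 0.0156, and from −0.384 to 0.578 on leaving out each preparation. With all summits it was −0.998 for tumor against GNP and −0.726 for tumor against hyperplasia, and the difference between genes for tumor against hyperplasia ran from −0.546 to 1.10 on leaving out each preparation.

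For the 27 called results of named genes, 670 values under the alternatives held 302 with the same call, 364 with the same direction and no call, and 4 reversed. The calls kept most often were Agbl4 in tumor against GNP (21 of 25) and Slc38a11 (21 of 22 in tumor against GNP, 19 of 22 in hyperplasia against GNP). Alternatives in which a gene fell below the filter were left out of these numbers, and Slc38a11 had fewer than Agbl4 for that reason. For the 112 results without a call, 2586 of 2789 values kept their sign and side, 23 passed the threshold and 180 changed sign. The alternatives planned for motifs were not run, and start sites were replaced by gene spans. The unknown depth and the lowest listed score limit what a missing summit can show.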

Other observations

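The splits for genes and gene lists and the exchanges of targets were chosen only after the results were seen, and the splits for regions were fixed beforehand, though how to read them was written after.

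The 6 preparations of a pair of stages can be split 3 against 3 in 10 ways, too few for a share under 0.05. The number of genes was 9 for hyperplasia against GNP, 13 for tumor against GNP and 5 for tumor against hyperplasia. Only the split by stage itself gave as many, and the highest of the others gave 1, 0 and 1. The number of gene lists, here adjusted over the 13 lists of a contrast, was 1 for tumor against GNP (highest other split 0). It was 1 for tumor against hyperplasia (2 splits as large, that by stage included, highest other 1). For hyperplasia against GNP the stage split called 0 lists. There the splits with GNP preparations 1 and 2 beside hyperplasia preparation 1 or 2 called 1 list each, so such calls also arose without a split by stage. The number of regions restricted to a stage was 2071, 2023 and 956. Only the split by stage itself was as large in each case, and the highest of the others gave 341, 380 and 366.

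For NFIA against NFIB, 0 genes were called by title (limma, 482 at an unadjusted p under 0.05), so that 100 of 100 exchanges of the targets within preparations gave as many by construction, which decides nothing; the highest of the others called 1.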
